A study of Homo sapiens with 21 samples.

How the data were processed

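RNA from 21 AU565 samples was extracted with TRIzol and sequenced as total RNA libraries (TruSeq), per the labels. The deposited table holds gene counts, which the submitters' processing notes credit to featureCounts on hg38, with limma also named and no versions given. It lists 16553 genes by Entrez identifier, 174 of them without a symbol, and none with a maximum under 0.501 CPM, so genes of lower level were not in the file. Columns were matched to samples by title. The columns of the primed aggregates carry the word primed, which their titles lack, and were taken as those samples by elimination. Positions come from the RefSeq table of GRCh38.p14, which held 16373 of the 16553 identifiers and need not be the build's annotation used upstream.

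Genes were tested in edgeR 4.0.16 (R 4.3.3) on the counts, with TMM normalization, filterByExpr by group, 1 mean per group for all 7 groups in 1 fit (14 residual degrees of freedom), robust quasi-likelihood fits and two-sided tests, with p Benjamini-Hochberg adjusted over the 15969 genes tested in each comparison. The filter removed 584 genes with 0.0116% of the counts. There were 8 pairwise comparisons and 3 differences between responses. Before the data were examined, 37 gene lists were fixed, of which 29 pathway lists and 5 others had at least 5 tested members. Pathway lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Overlaps of calls used Fisher's exact test, two-sided. Panels of genes of other tissues were drawn up after the data were seen.

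The rule for named genes was fixed before the data were examined. It takes, per pairwise comparison, the 8 called genes with the largest rise and the 8 with the largest fall (4 each for differences between responses), with a mean of at least 1 CPM in 1 group and all 3 replicates of 1 group above those of the other, which chance gives in 10% of genes for 3 against 3. It leaves out clone names, LOC, LINC and MIR symbols and pseudogenes. It also takes the 3 members with the smallest p in each called list and 9 genes in every comparison. For length the text prints the first 3 or 4 each way, the first 2 members of a list, or the first or none of a list not called with an estimated correlation, and 8 of the 9 genes. A few genes that the rule takes are not reported here. A few others are named for their tissue and were chosen after their values were seen. Ranks rest on fitted changes. For a gene with no count in a group a lower bound against 3 counts over that group is given in their place, and for 1 to 3 counts the levels alone. Floors cover counting error only.

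Total counts were 15005070 to 26921113 per library. Replicate pairs differed by 2.4 to 10.7 times the variance of counting alone (chi-squared per degree of freedom over 21 pairs, genes of 20 counts or more), and the biological coefficient of variation was 5.98%. The same steps were tested on simulated data of the size of the acute comparison (15933 genes). They recovered 78% of 100 genes changed 1.5-fold and 84% of 100 changed 2-fold, with 4.23% of calls false. They called 1 list, whose 25 members were raised 1.25-fold, and 0 genes between unchanged groups. List calls among correlated genes were not tested.

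Alternatives fixed beforehand were DESeq2 1.42.0, limma voom, RLE size factors, no filter, a fit of only the groups compared, the replicate number as a block, leaving out each replicate, and a correlation estimated for each list. Added after the data were seen were genes averaging 10 CPM or more, leaving out the 6 libraries with striated muscle transcripts, and the overlap of acute and primed aggregate calls. No sample was left out of the values reported.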

Results

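RNA was sequenced from AU565, a breast cancer cell line with an amplified ERBB2 gene, grown as flat monolayers or as 3D aggregates in a liquid overlay with 5% matrigel, with or without trastuzumab, an antibody against the ERBB2 product HER2. The 21 libraries form 7 groups of 3. They are untreated monolayers, monolayers exposed acutely (20 µg/ml for 24 h), primed monolayers (the same exposure and 96 h more), untreated aggregates (96 h), primed aggregates (from cells exposed as a monolayer, then 96 h), treated aggregates (50 µg/ml for 24 h after 96 h), and aggregates both primed and treated. Whether the antibody was removed after priming is not stated, nor is the age of the untreated monolayers. The treated aggregates were also 24 h older than the untreated and the primed ones. Levels are counts scaled to library size (CPM) as group mean ± SD, n = 3, and changes are log2 fold changes with their standard error (SE); a lone value after a gene's name is its log2 fold change. A gene passed with a Benjamini-Hochberg adjusted p under 0.05. The labels do not say that replicates came from separate cultures, so the tests measure the spread between these samples, which can be technical.

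**Figure D1:**
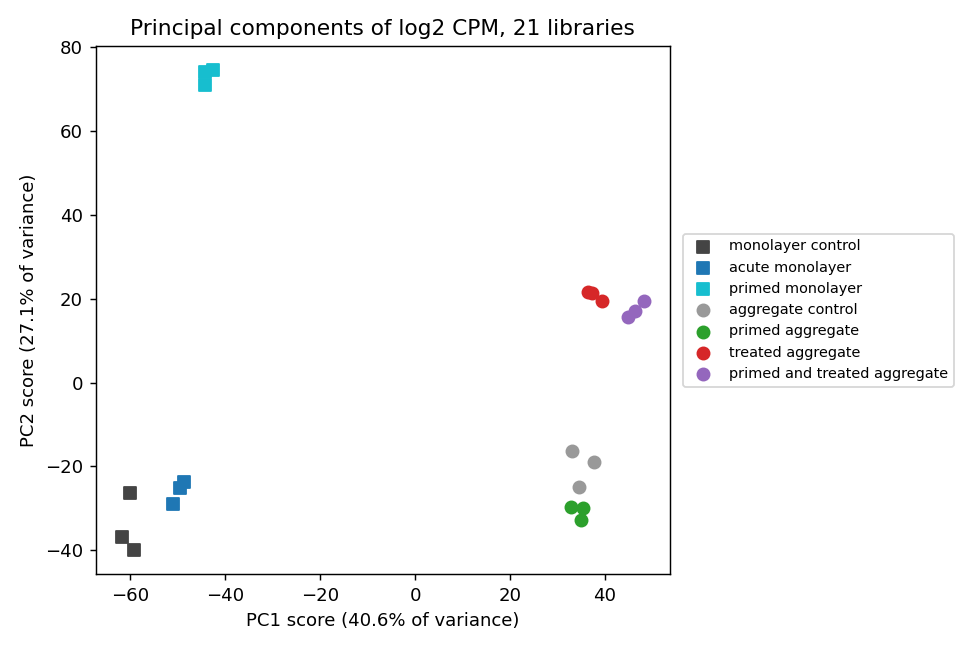
Each point is 1 of the 21 libraries on the first and second principal components of log2 CPM, which hold 40.6% and 27.1% of the variance; squares are monolayers and circles aggregates. Monolayers lie on the negative side of the first component and aggregates on the positive side, and the second separates the primed monolayers, the treated and the primed and treated aggregates from the other 4 groups.

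Transcripts typical of other tissues split the libraries into 2 sets. The 12 libraries of untreated and acutely exposed monolayers and of untreated and primed aggregates carried the melanin synthesis enzyme TYRP1 at 5.73 to 33.5 CPM and the matrix protein POSTN at 11 to 30. In the 9 libraries of primed monolayers, treated aggregates and primed and treated aggregates these were at most 0.261 and 0.137. Those 9 carried the kidney protein UMOD at 0.825 to 22.9 CPM and the synaptic protein SNAP25 at 4.33 to 17.3, against at most 0.059 and 0.526 in the 12. The cardiac myosin MYH7 was at 20.6 to 90.7 CPM in 6 libraries (replicates 1 and 2 of the untreated monolayers, 2 and 3 of the acutely exposed monolayers, 1 and 2 of the untreated aggregates) and at most 0.111 in the other 15. In panels of tissue genes drawn up after the data were seen, 10 of 16 kidney and 8 of 12 brain genes were over 5-fold higher in the 3 groups, and 8 of 12 striated muscle, 7 of 9 melanocyte and 7 of 14 mesenchymal genes in the other 4. The mitochondrial rRNA share was 0.793 to 1.14% of counts in monolayers, 2.5 to 2.77% in untreated and primed aggregates, 1.52 to 1.71% in treated and 2.13 to 2.36% in primed and treated aggregates. A comparison between the sets cannot tell the set from the treatment, since no group has libraries in both and no fit with the set as a term can be had. Gene and list counts and named genes were also tested without the 6 libraries with MYH7, an alternative chosen after the data were seen; values beside genes that did not pass in an alternative are its log2 fold changes.

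**Figure D2:**
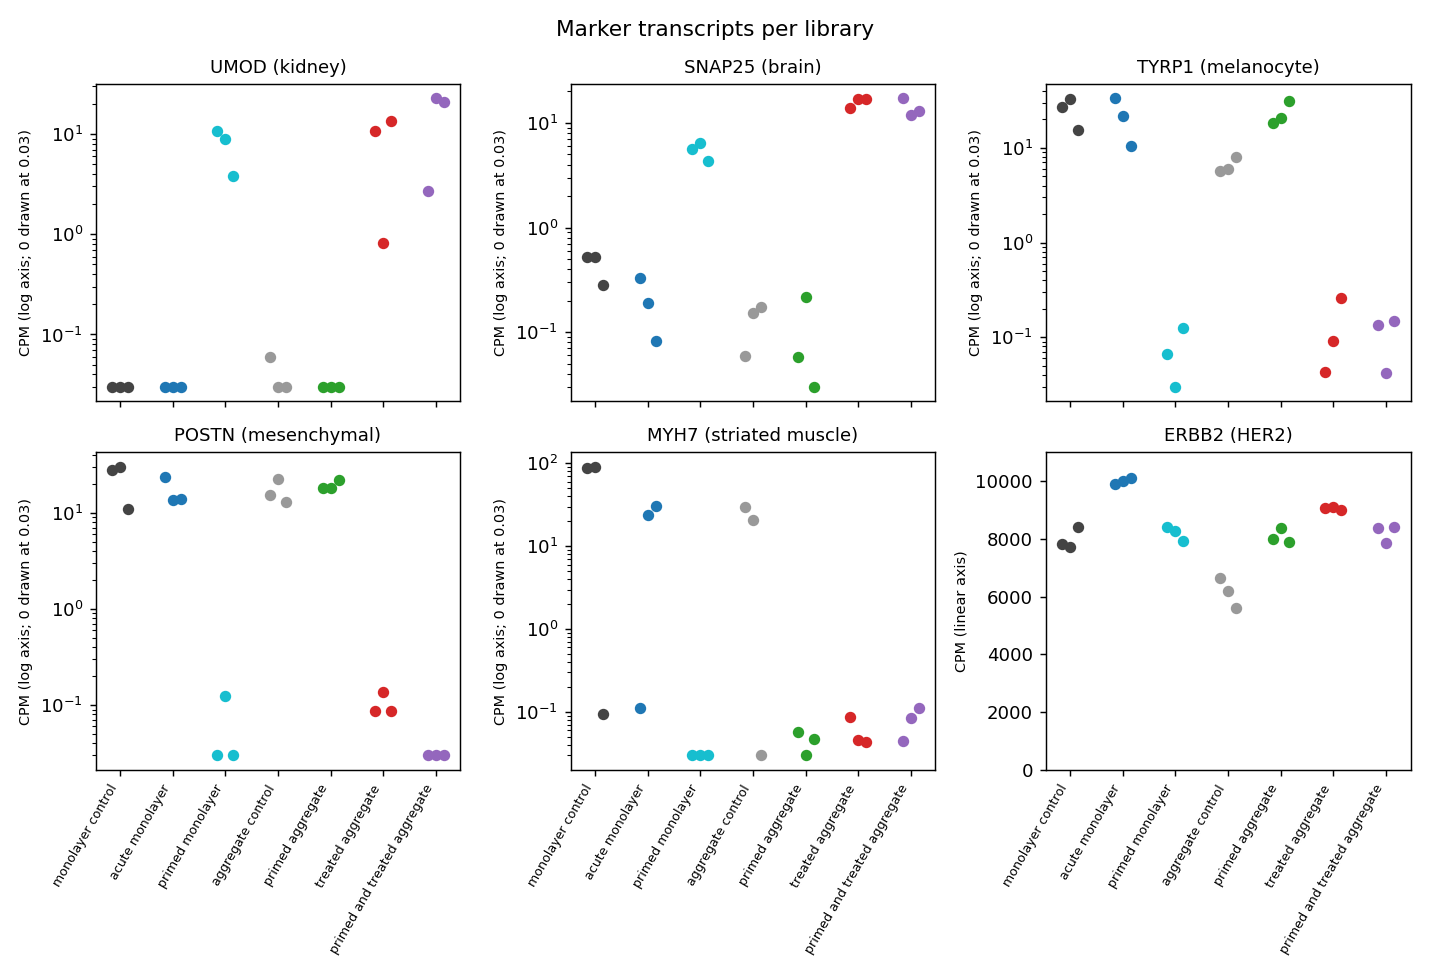
CPM of UMOD, SNAP25, TYRP1, POSTN and MYH7 (log axis, 0 drawn at 0.03) and of ERBB2 (linear axis) in each library, 1 point per library, by group. MYH7 lies at 20.6 or more in 6 libraries and at 0.111 or less in the other 15.

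Untreated aggregates were compared with untreated monolayers, to ask what growth in 3D alone changes. EGLN3, an oxygen-sensing prolyl hydroxylase, averaged 227 ± 16.8 CPM against 10.3 ± 0.8 (log2 4.47, SE 0.082, edgeR adjusted p = 2.54e-30). The proliferation marker MKI67 averaged 32.4 ± 3.26 CPM against 193 ± 5.28 (log2 −2.57, SE 0.10, edgeR adjusted p = 4.17e-15). ERBB2 (Entrez 2064, chromosome 17, 39688094 to 39728658 on GRCh38) was lower in aggregates, at 6189 ± 426 CPM against 7732 ± 402 (log2 −0.32, SE 0.053, edgeR adjusted p = 2.4e-06), and the metallothionein MT1X higher, at 14.7 ± 0.605 CPM against 0.285 ± 0.103 (log2 5.63, SE 0.21, edgeR adjusted p = 7.69e-22). 21 of 24 hypoxia and 17 of 19 glycolysis genes rose by edgeR, and 27 of 27 G2/M genes fell. In all, 10229 of 15969 genes passed, 5256 higher and 4973 lower. The largest rises were in the nucleoside transporter SLC28A1 (5.67), MT1X (5.63) and the liprin PPFIA4 (5.26). Nearly absent from untreated monolayers, the phospholipase PLA2G4D averaged 1.24 ± 0.27 CPM against 0.0154 ± 0.0267. The largest falls were in the metalloprotease family member ADAM23 (−5.03). Absent from all 3 libraries of untreated aggregates, the ion channel subunit CNGA2 was at least 22.8-fold lower and CLEC3A at least 21.3-fold. Nearly absent from untreated aggregates, CRTAC1 averaged 0.0196 ± 0.0339 CPM against 1.83 ± 1.12. Among the receptor, cell cycle and immune genes followed throughout, the receptor EGFR (1.86), the HER2 partner ERBB3 (0.29), the CDK inhibitor CDKN1B (0.42) and the angiogenic factor VEGFA (1.13) rose. The G1 cyclin CCND1 (0.067, adjusted p = 0.203) and the checkpoint ligand CD274 (0.013, adjusted p = 0.968) did not pass in edgeR.

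Camera called 13 of 29 lists, 7 higher and 6 lower. Camera asks whether a list's members stand apart from all other tested genes. Here and in every other comparison, a called list with no p given for an estimated correlation kept its call with it. Members not counted as risen or fallen did not pass, and counts adjusted over the list alone are given where they differ from those over all genes. The MAPK feedback list, immediate early genes and MAPK feedback inhibitors, was shifted up (camera adjusted p = 1.48e-07). Of 24 members 14 rose and 5 fell, with the ETS factor ETV4 (3.11) and the AP-1 subunit FOS (3.99). In the G2/M list, mitotic cyclins, kinases and spindle proteins, 0 of 27 members rose and 27 fell. It was shifted down (camera adjusted p = 2.84e-51), with the mitotic transcription factor FOXM1 (−2.45) and the mitotic cyclin CCNB1 (−2.03). EGLN3 (4.47) and the collagen prolyl hydroxylase P4HA1 (2.70) led the hypoxia list, targets of the oxygen-sensing HIF factors. Of 24 members 21 rose and 0 fell, a shift up (camera adjusted p = 2.18e-28). The glycolysis list, enzymes and transporters from glucose to lactate, was shifted up (camera adjusted p = 4.14e-15). Of 19 members 17 rose and 1 fell, with the aldolase ALDOC (2.50) and ALDOA (1.51).

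In the cholesterol synthesis list, sterol enzymes, uptake and their regulators, 1 of 24 members rose and 19 fell. It was shifted down (camera adjusted p = 2.87e-06), with farnesyl diphosphate synthase FDPS (−1.35). The autophagy and lysosome list, genes of the degradation machinery, was shifted down (camera adjusted p = 0.00322). Of 24 members 5 rose and 14 fell, with the lysosomal protease CTSA (−1.13). Higher at the preset correlation only were FOXO and PI3K feedback (genes held down by PI3K signalling, 16 of 24 rose and 3 fell, camera adjusted p = 0.000721, with the HIF-induced regulator CITED2 at 1.51), luminal differentiation (markers of secretory mammary epithelium, 12 of 21 rose and 7 fell, camera adjusted p = 0.00978, with the mucin MUC1 at 2.23), ATF4 and unfolded protein (stress responses of the ER and of amino acid supply, 19 of 26 rose and 3 fell, camera adjusted p = 2.42e-05, with the lipoprotein receptor VLDLR at 3.08) and MYC and ribosome biogenesis (nucleolar and growth genes, 15 of 26 rose and 3 fell, 16 and 3 over the list alone, camera adjusted p = 0.00655, with the pyrimidine synthesis enzyme CAD at 0.93). In turn, these lists had adjusted p = 0.054, 0.21, 0.21 and 0.14 with an estimated correlation. At the preset correlation only, those called lower were G1/S (replication factors and their regulators, 1 of 27 rose and 25 fell, camera adjusted p = 1.48e-07, with the replication licensing factor CDC6 at −1.23), fatty acid synthesis (lipogenic enzymes, 3 of 18 rose and 12 fell, camera adjusted p = 0.0179, with stearoyl-CoA desaturase SCD at −0.98) and heat shock (cytosolic chaperones, 2 of 16 rose and 10 fell, camera adjusted p = 0.00149, with the chaperone HSPH1 at −1.35). As listed, they had adjusted p = 0.076, 0.054 and 0.19 with an estimated correlation. Both groups belong to the set of 12 libraries, but the age of the monolayers is not given, and ADAM23 and CRTAC1 fell along with the melanocyte panel (summed 63.7 to 134 CPM in monolayers and 26.9 to 38 in aggregates). ERBB3 (0.20) did not pass without the MYH7 libraries.

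Acutely exposed and untreated monolayers were compared for the response to 24 h of trastuzumab. SPRY4, a feedback inhibitor of receptor signalling, averaged 108 ± 3.46 CPM against 22.4 ± 0.579 (log2 2.27, SE 0.067, edgeR adjusted p = 2.08e-23). The insulin receptor INSR averaged 60.3 ± 0.223 CPM against 15.5 ± 1.69 (log2 1.95, SE 0.082, edgeR adjusted p = 7.05e-19). ERBB2 averaged 9937 ± 117 CPM against 7732 ± 402 (log2 0.36, SE 0.053, edgeR adjusted p = 2.98e-06), and GRB7, an adaptor that binds HER2 and whose gene lies beside ERBB2, 1370.0 ± 4.15 CPM against 742 ± 37.2 (log2 0.89, SE 0.054, edgeR adjusted p = 1.17e-14). 15 of 24 MAPK feedback and 13 of 24 FOXO genes rose by edgeR, and 14 of 24 cholesterol synthesis genes fell. The edgeR test called 3222 genes, 1799 higher and 1423 lower. Those with the largest rises included the keratin KRT23 (2.90), SPRY4 (2.27), the adenosine receptor ADORA1 (2.25) and the cAMP-activated exchange factor RAPGEF3 (2.22). The largest falls included ANKRD30B (−2.65), the collagen COL1A2 (−2.19), CLEC3A (−2.02) and the transglutaminase TGM3 (−1.88). Of the genes followed in each comparison, EGFR (0.23), ERBB3 (0.51), CCND1 (0.43), CDKN1B (0.21) and VEGFA (0.51) rose. MKI67 (−0.23, adjusted p = 0.086) and CD274 (−0.33, adjusted p = 0.379) did not pass in edgeR.

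Of 29 lists, 13 were called by camera, 9 higher and 4 lower. In the HER family list, ERBB receptors, ligands and regulators, 6 of 16 members rose and 1 fell (6 and 2 over the list alone). It was shifted up (camera adjusted p = 5.85e-06), with GRB7 (0.89) and the receptor feedback inhibitor ERRFI1 (0.996). INSR (1.95) and the transcription factor FOXO3 (0.88) led the FOXO and PI3K feedback list. Of 24 members 13 rose and 0 fell (14 and 0 over the list alone), a shift up (camera adjusted p = 1.78e-13). The MAPK feedback list was shifted up (camera adjusted p = 1.93e-29). Of 24 members 15 rose and 0 fell (17 and 0 over the list alone), with SPRY4 (2.27) and ETV4 (1.82). In the cholesterol synthesis list 1 of 24 members rose and 14 fell (1 and 15 over the list alone). The shift was down (camera adjusted p = 1.08e-07), with FDPS (−0.52) and the sterol carrier STARD4 (−0.82). Plakoglobin JUP (0.68) and periplakin PPL (0.44) led the epithelial junction list, tight junction and desmosome proteins. Of 25 members 9 rose and 0 fell (11 and 0 over the list alone), a shift up (camera adjusted p = 0.000111).

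The integrin and basement membrane list, matrix receptors and their ligands, was shifted up (camera adjusted p = 0.000408). Of 30 members 10 rose and 2 fell (11 and 2 over the list alone), with the integrin subunit ITGB5 (0.90) and the syndecan SDC1 (0.93). In the luminal differentiation list 7 of 21 members rose and 0 fell (9 and 0 over the list alone). It was shifted up (camera adjusted p = 1.88e-05), with the epithelial ETS factor ELF3 (0.84) and KRT23 (2.90). The Notch target HES1 (0.68) and the aldehyde dehydrogenase ALDH1A3 (0.62) led the stem cell list, genes used as stem cell markers. Of 18 members 9 rose and 2 fell, a shift up (camera adjusted p = 0.00145). Called higher with the preset correlation alone were chemokine and cytokine (secreted signals, 3 of 16 rose and 0 fell, camera adjusted p = 0.00635, with VEGFA at 0.51) and NF-kB target (inflammatory response genes, 6 of 17 rose and 0 fell, 8 and 0 over the list alone, camera adjusted p = 0.0022, with the NF-kB inhibitor NFKBIA at 0.43). Taken one by one, adjusted p = 0.19 and 0.13 with an estimated correlation. Lower at the preset correlation only were G1/S (0 of 27 rose and 10 fell, 0 and 12 over the list alone, camera adjusted p = 0.000111, with the clamp loader subunit RFC3 at −0.44), G2/M (0 of 27 rose and 20 fell, 0 and 21 over the list alone, camera adjusted p = 3.37e-09, with the mitotic kinase AURKA at −0.39) and oxidative phosphorylation (nuclear-encoded respiratory chain subunits, 0 of 28 rose and 12 fell, 0 and 15 over the list alone, camera adjusted p = 2.82e-05, with cytochrome c CYCS at −0.29). In this order, adjusted p = 0.17, 0.12 and 0.25 with an estimated correlation. MYH7 was present in both groups, in replicates 1 and 2 of the untreated and 2 and 3 of the exposed monolayers, and COL1A2 is a mesenchymal gene. Without the 6 libraries with MYH7, 1 library per group was left, assumed to vary like the rest, and 727 genes passed, 525 higher and 202 lower. ANKRD30B (−0.48), COL1A2 (−1.40), TGM3 (−2.76), ERBB2 (0.26), EGFR (0.14) and CDKN1B (0.10) did not pass without the MYH7 libraries and MKI67 passed with limma voom, with DESeq2, with only the compared groups fitted and among genes averaging 10 CPM or more.

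Primed monolayers, exposed for 24 h and kept 96 h more, were compared with untreated monolayers to ask what remained of the exposure. MCM3, a subunit of the replicative helicase, averaged 94.9 ± 1.43 CPM against 29.9 ± 0.451 (log2 1.67, SE 0.069, edgeR adjusted p = 1.34e-20). MYC, a regulator of growth, averaged 257 ± 14.2 CPM against 101 ± 5.16 (log2 1.34, SE 0.056, edgeR adjusted p = 1.49e-20). ERBB2 averaged 8353 ± 316 CPM against 7732 ± 402 and did not pass (log2 0.11, SE 0.053, edgeR adjusted p = 0.0627). 26 of 27 G1/S and 12 of 15 basal and squamous genes rose by edgeR. In all, 10431 of 15969 genes passed, 5382 higher and 5049 lower. Absent from all 3 libraries of untreated monolayers, UMOD was at least 164-fold higher, the interleukin antagonist IL36RN at least 30-fold and ACSM2A at least 26-fold. Absent from all 3 libraries of primed monolayers, MYH7 was at least 935-fold lower and the melanosome receptor GPR143 at least 60.3-fold. Nearly absent from primed monolayers, POSTN averaged 0.0426 ± 0.0737 CPM against 22.1 ± 9.9. For the other genes followed throughout, EGFR (1.34), ERBB3 (0.65), CCND1 (0.84) and MKI67 (0.65) rose and CDKN1B (−0.14) and VEGFA (−0.60) fell. CD274 (−0.044, adjusted p = 0.887) did not pass in edgeR.

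Camera called 13 of 29 lists, 11 higher and 2 lower. MCM3 (1.67) and the flap endonuclease FEN1 (1.31) led the G1/S list. Of 27 members 26 rose and 0 fell, a shift up (camera adjusted p = 1.44e-16). The basal and squamous list, keratins and cornified envelope genes, was shifted up (camera adjusted p = 4.34e-05). Of 15 members 12 rose and 0 fell, with involucrin IVL (6.51) and the keratin KRT16 (5.47).

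At the preset correlation only, those called higher were MAPK feedback (15 of 24 rose and 4 fell, camera adjusted p = 0.00374), G2/M (18 of 27 rose and 3 fell, camera adjusted p = 0.0246), chemokine and cytokine (10 of 16 rose and 3 fell, camera adjusted p = 0.0112), NF-kB target (12 of 17 rose and 0 fell, camera adjusted p = 0.000153), epithelial junction (17 of 25 rose and 2 fell, 19 and 3 over the list alone, camera adjusted p = 0.000182), integrin and basement membrane (20 of 30 rose and 5 fell, camera adjusted p = 0.000478), YAP/TAZ and actin (genes responsive to cell tension, 15 of 23 rose and 5 fell, 16 and 5 over the list alone, camera adjusted p = 1.18e-08), stem cell (10 of 18 rose and 6 fell, camera adjusted p = 0.0133) and MYC and ribosome biogenesis (21 of 26 rose and 2 fell, camera adjusted p = 6.89e-05). In turn, these lists had adjusted p = 0.16, 0.51, 0.24, 0.058, 0.052, 0.058, 0.058, 0.052 and 0.052 with an estimated correlation. Called lower with the preset correlation alone were ATF4 and unfolded protein (4 of 26 rose and 15 fell, camera adjusted p = 0.00374) and autophagy and lysosome (5 of 24 rose and 16 fell, camera adjusted p = 0.0356). As listed, they had adjusted p = 0.45 and 0.13 with an estimated correlation. The falls of TYRP1, GPR143, PAX3 and POSTN and the rises of UMOD, CDH16 and UGT2B7 separate the sets. The groups fell in different library sets, and the age of the untreated monolayers is not given. UMOD and CDKN1B (−0.16) did not pass without the MYH7 libraries, MYH7 did not pass with limma voom and ERBB2 passed with limma voom.

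Aggregates grown from primed cells were compared with untreated aggregates, to ask what a past exposure left in 3D culture. ERBB2 averaged 8274 ± 281 CPM against 6189 ± 426 (log2 0.42, SE 0.053, edgeR adjusted p = 4.67e-07), GRB7 1307 ± 75.1 CPM against 778 ± 55.8 (log2 0.75, SE 0.054, edgeR adjusted p = 5.69e-12) and the HER2 partner ERBB3 551 ± 25.3 CPM against 348 ± 3.47 (log2 0.66, SE 0.051, edgeR adjusted p = 1.56e-11). EGLN3 averaged 119.6 ± 4.45 CPM against 227 ± 16.8 (log2 −0.93, SE 0.065, edgeR adjusted p = 5.69e-12). 18 of 24 hypoxia and 14 of 19 glycolysis genes fell by edgeR, and 12 of 24 FOXO genes rose. The edgeR test called 3379 genes, 1836 higher and 1543 lower. The largest rises were in ADAM23 (5.03) and the serotonin receptor HTR2B (3.59). With few counts in untreated aggregates, CRTAC1 averaged 1.90 ± 0.958 CPM against 0.0196 ± 0.0339 and ISM1 1.19 ± 0.386 against 0.0536 ± 0.0513. The largest falls were in desmin DES (−2.73), LRTM2 (−1.78), SLC36A2 (−1.74) and adrenomedullin ADM (−1.66). Among the receptor, cell cycle and immune genes followed throughout, CDKN1B (0.22) rose and VEGFA (−0.32) fell. EGFR (0.040, adjusted p = 0.705), CCND1 (0.014, adjusted p = 0.87), MKI67 (0.27, adjusted p = 0.0821) and CD274 (−0.041, adjusted p = 0.933) did not pass in edgeR.

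Of 29 lists, 15 were called by camera, 7 higher and 8 lower. The HER family list was shifted up (camera adjusted p = 0.00018). Of 16 members 5 rose and 0 fell (6 and 0 over the list alone), with GRB7 (0.75) and ERBB3 (0.66). In the FOXO and PI3K feedback list 12 of 24 members rose and 3 fell (14 and 5 over the list alone). The shift was up (camera adjusted p = 9.73e-06), with CITED2 (−0.97) and ERBB3 (0.66). EGLN3 (−0.93) and the prolyl hydroxylase EGLN1 (−0.55) led the hypoxia list. Of 24 members 1 rose and 18 fell (2 and 19 over the list alone), a shift down (camera adjusted p = 8.76e-19). The glycolysis list was shifted down (camera adjusted p = 3.74e-14). Of 19 members 1 rose and 14 fell (3 and 14 over the list alone), with phosphoglycerate kinase PGK1 (−0.60) and ALDOC (−0.44). In the epithelial junction list 13 of 25 members rose and 2 fell (16 and 3 over the list alone). It was shifted up (camera adjusted p = 0.00018), with the desmoglein DSG2 (0.31).

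ITGB5 (0.46) and the laminin LAMB2 (0.46) led the integrin and basement membrane list. Of 30 members 13 rose and 0 fell (13 and 1 over the list alone), a shift up (camera adjusted p = 4.84e-05). The NRF2 list, antioxidant and detoxifying enzymes, was shifted down (camera adjusted p = 1.51e-05). Of 23 members 2 rose and 11 fell, with phosphogluconate dehydrogenase PGD (−0.35) and the efflux transporter ABCC3 (0.55). Higher at the preset correlation only were G2/M (7 of 27 rose and 0 fell, 8 and 0 over the list alone, camera adjusted p = 0.00481, with the kinetochore protein CENPF at 0.62), type I interferon (antiviral genes, 12 of 30 rose and 2 fell, 14 and 2 over the list alone, camera adjusted p = 0.000169, with the antiviral synthetase OAS1 at 0.70) and YAP/TAZ and actin (9 of 23 rose and 2 fell, 9 and 3 over the list alone, camera adjusted p = 0.0111, with the BMP-binding protein CRIM1 at 0.70). Taken one by one, adjusted p = 0.42, 0.086 and 0.38 with an estimated correlation. At the preset correlation only, those called lower were G1/S (0 of 27 rose and 10 fell, 0 and 11 over the list alone, camera adjusted p = 9.73e-06, with CDC6 at −0.62), oxidative phosphorylation (0 of 28 rose and 14 fell, 0 and 15 over the list alone, camera adjusted p = 9.21e-06, with the ATP synthase subunit ATP5MC1 at −0.39), basal and squamous (0 of 15 rose and 4 fell, 0 and 5 over the list alone, camera adjusted p = 0.0176, with the keratin KRT15 at −0.80), heat shock (0 of 16 rose and 5 fell, camera adjusted p = 0.0133, with the chaperone HSPA8 at −0.36) and MYC and ribosome biogenesis (1 of 26 rose and 7 fell, 2 and 9 over the list alone, camera adjusted p = 0.000661, with ornithine decarboxylase ODC1 at −0.85). In this order, adjusted p = 0.12, 0.22, 0.14, 0.31 and 0.079 with an estimated correlation. The melanosome transporter SLC45A2 rose (2.90), and TYRP1 averaged 23.9 ± 7.21 CPM in primed and 6.63 ± 1.37 in untreated aggregates, while the muscle gene DES fell (−2.73) and MYH7 was present in 2 of the 3 untreated aggregates. With only the groups compared in the fit, 2177 genes passed, and without the 6 libraries with MYH7 2176. DES did not pass with limma voom (−2.58) and without the MYH7 libraries (−1.58), DSG2 (0.24), CDKN1B (0.14) and VEGFA (−0.074) did not pass without the MYH7 libraries and MKI67 passed with DESeq2.

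Treated aggregates were compared with untreated ones for the response of formed aggregates to 24 h of trastuzumab. ERBB2 averaged 8992 ± 140.0 CPM against 6189 ± 426 (log2 0.54, SE 0.053, edgeR adjusted p = 6.7e-10) and GRB7 1294 ± 22.7 CPM against 778 ± 55.8 (log2 0.73, SE 0.054, edgeR adjusted p = 7.07e-13). EGLN3 averaged 72.3 ± 5.43 CPM against 227 ± 16.8 (log2 −1.65, SE 0.066, edgeR adjusted p = 4.08e-19), and MKI67 54.2 ± 6.67 CPM against 32.4 ± 3.26 (log2 0.74, SE 0.11, edgeR adjusted p = 1.19e-05). 20 of 24 hypoxia and 14 of 19 glycolysis genes fell by edgeR, and 23 of 27 G2/M genes rose. In all, 5856 of 15969 genes passed, 2996 higher and 2860 lower. Absent from all 3 libraries of untreated aggregates, the immunoglobulin light chain IGKC was at least 49.3-fold higher, NAT8 at least 48.2-fold and ACSM2A at least 45.8-fold. The largest falls included POSTN (−7.29) and TYRP1 (−5.59). Absent from all 3 libraries of treated aggregates, the developmental transcription factor ISL1 was at least 51-fold lower. Of the genes followed in each comparison, ERBB3 (0.52) and CCND1 (0.22) rose and EGFR (−0.42), CDKN1B (−0.26) and VEGFA (−0.68) fell. CD274 (−0.58, adjusted p = 0.0639) did not pass in edgeR.

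Camera called 11 of 29 lists, 6 higher and 5 lower. In the hypoxia list 0 of 24 members rose and 20 fell. It was shifted down (camera adjusted p = 2.09e-34), with EGLN3 (−1.65) and the stress-induced NDRG1 (−0.95). The integrin subunit ITGB4 (1.35) and the laminin LAMB1 (0.52) led the integrin and basement membrane list. Of 30 members 18 rose and 0 fell (19 and 0 over the list alone), a shift up (camera adjusted p = 1.32e-06). The MYC and ribosome biogenesis list was shifted down (camera adjusted p = 1.04e-06). Of 26 members 0 rose and 18 fell (1 and 18 over the list alone), with fibrillarin FBL (−0.66) and the nucleolar protein NOP2 (−0.43).

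In the autophagy and lysosome list 10 of 24 members rose and 1 fell. It was shifted up (camera adjusted p = 0.00188), with the lysosomal membrane protein LAMP1 (0.66) and CTSA (0.60). Called higher with the preset correlation alone were HER family (5 of 16 rose and 2 fell, camera adjusted p = 0.0282, median 0.30 and mean −0.17), G2/M (23 of 27 rose and 0 fell, 25 and 0 over the list alone, camera adjusted p = 5.36e-13), luminal differentiation (12 of 21 rose and 2 fell, camera adjusted p = 0.00265) and stem cell (7 of 18 rose and 4 fell, camera adjusted p = 0.0237). In turn, these lists had adjusted p = 0.14, 0.062, 0.18 and 0.061 with an estimated correlation. Lower at the preset correlation only were glycolysis (1 of 19 rose and 14 fell, camera adjusted p = 5.36e-13), oxidative phosphorylation (0 of 28 rose and 15 fell, camera adjusted p = 0.00164) and ATF4 and unfolded protein (2 of 26 rose and 14 fell, camera adjusted p = 9.55e-06). As listed, they had adjusted p = 0.051, 0.43 and 0.27 with an estimated correlation. Kidney genes (AQP2, UGT2B7, ACSM2A) and brain CPLX2 among the rises, and POSTN and TYRP1 among the falls, separate the 2 sets. The groups fell in different library sets and the treated aggregates were 24 h older. IGKC, NAT8, AQP2 and CCND1 (0.15) did not pass without the MYH7 libraries.

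Aggregates both primed and treated were compared with those that had neither exposure. ERBB2 averaged 8198 ± 310.0 CPM against 6189 ± 426 (log2 0.41, SE 0.053, edgeR adjusted p = 2.17e-07) and EGLN3 69.7 ± 4.99 CPM against 227 ± 16.8 (log2 −1.70, SE 0.066, edgeR adjusted p = 1.54e-19). The ribonucleotide reductase subunit RRM2 averaged 12.1 ± 2.05 CPM against 24.6 ± 0.982 (log2 −1.02, SE 0.11, edgeR adjusted p = 3.78e-08), while MKI67 at 30.9 ± 1.71 CPM against 32.4 ± 3.26 did not pass (log2 −0.072, SE 0.11, edgeR adjusted p = 0.648). 19 of 24 hypoxia and 18 of 27 G1/S genes fell by edgeR. The edgeR test called 5671 genes, 2812 higher and 2859 lower. With no count in untreated aggregates, NAT8 was at least 38.3-fold higher and complexin CPLX2 at least 31.9-fold. With few counts in untreated aggregates, UMOD averaged 15.5 ± 11.1 CPM against 0.0196 ± 0.0339. With no count in primed and treated aggregates, POSTN was at least 415-fold lower, ISL1 at least 54.7-fold and the granzyme inhibitor SERPINB9 at least 33.9-fold. For the other genes followed throughout, ERBB3 (0.57) rose and EGFR (−0.30) and VEGFA (−0.53) fell. CCND1 (0.010, adjusted p = 0.887), CDKN1B (−0.080, adjusted p = 0.301) and CD274 (−0.24, adjusted p = 0.461) did not pass in edgeR.

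Of 29 lists, 10 were called by camera, 2 higher and 8 lower. EGLN3 (−1.70) and NDRG1 (−0.89) led the hypoxia list. Of 24 members 0 rose and 19 fell (0 and 21 over the list alone), a shift down (camera adjusted p = 7.22e-29). At the preset correlation only, those called higher were FOXO and PI3K feedback (13 of 24 rose and 4 fell, camera adjusted p = 0.000202) and epithelial junction (12 of 25 rose and 3 fell, camera adjusted p = 0.0295, median 0.13 and mean −0.026). Taken one by one, adjusted p = 0.088 and 0.19 with an estimated correlation.

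Called lower with the preset correlation alone were G1/S (1 of 27 rose and 18 fell, camera adjusted p = 5.54e-07), glycolysis (1 of 19 rose and 13 fell, camera adjusted p = 2.79e-09), oxidative phosphorylation (0 of 28 rose and 15 fell, 0 and 17 over the list alone, camera adjusted p = 3.56e-05), cholesterol synthesis (1 of 24 rose and 13 fell, 2 and 13 over the list alone, camera adjusted p = 0.00345), mesenchymal transition (mesenchymal matrix and regulatory genes, 1 of 20 rose and 9 fell, camera adjusted p = 0.0295), ATF4 and unfolded protein (2 of 26 rose and 17 fell, 2 and 18 over the list alone, camera adjusted p = 1.07e-07) and MYC and ribosome biogenesis (0 of 26 rose and 13 fell, 0 and 14 over the list alone, camera adjusted p = 3.56e-05). In this order, adjusted p = 0.13, 0.13, 0.29, 0.13, 0.29, 0.15 and 0.088 with an estimated correlation. ACTA2, COL3A1, POSTN and TYRP1 among the falls and UMOD, AQP2 and CPLX2 among the rises separate the 2 sets. Set and age differed as in the comparison of treated with untreated aggregates. UMOD did not pass with limma voom and without the MYH7 libraries, NAT8 did not pass with only the compared groups fitted and without the MYH7 libraries and AQP2 did not pass without the MYH7 libraries.

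Primed and treated aggregates were compared with treated ones of the same age and library set, to ask what priming changes in the response to a later dose. MKI67 averaged 30.9 ± 1.71 CPM against 54.2 ± 6.67 (log2 −0.81, SE 0.10, edgeR adjusted p = 2.48e-05). FOXM1, a transcription factor of mitotic genes, averaged 11.8 ± 1.5 CPM against 22.3 ± 1.21 (log2 −0.91, SE 0.083, edgeR adjusted p = 8.32e-09), and RRM2 12.1 ± 2.05 CPM against 25.0 ± 3.13 (log2 −1.04, SE 0.11, edgeR adjusted p = 3.14e-07). 26 of 27 G2/M and 14 of 27 G1/S genes fell by edgeR. ERBB2 averaged 8198 ± 310.0 CPM against 8992 ± 140.0 and did not pass (log2 −0.13, SE 0.053, edgeR adjusted p = 0.122). In all, 1274 of 15969 genes passed, 508 higher and 766 lower. The largest rises were in the metallothionein MT1G (1.81), the aryl hydrocarbon receptor target CYP1A1 (1.48), the GABA receptor subunit GABRR2 (1.48) and NR2F2-AS1 (1.38). The largest falls were in lactoferrin LTF (−4.97), the scaffold protein AKAP12 (−3.46), the acyl-CoA synthetase ACSL4 (−2.93) and the kidney endocytic receptor megalin LRP2 (−2.69). Among the receptor, cell cycle and immune genes followed throughout, CDKN1B (0.18) rose and CCND1 (−0.21) fell. EGFR (0.12, adjusted p = 0.239), ERBB3 (0.043, adjusted p = 0.698), CD274 (0.34, adjusted p = 0.469) and VEGFA (0.15, adjusted p = 0.18) did not pass in edgeR.

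Camera called 12 of 29 lists, 3 higher and 9 lower. The G1/S list was shifted down (camera adjusted p = 1.04e-14). Of 27 members 0 rose and 14 fell (0 and 16 over the list alone), with CDC6 (−0.66) and RRM2 (−1.04). In the G2/M list 0 of 27 members rose and 26 fell. The shift was down (camera adjusted p = 1.1e-59), with FOXM1 (−0.91) and the mitotic ubiquitin ligase activator CDC20 (−0.74). The cholesterol synthesis list was shifted down (camera adjusted p = 0.000225). Of 24 members 0 rose and 6 fell (1 and 10 over the list alone), with the sterol reductase DHCR7 (−0.33). The fatty acid synthesis list was shifted down (camera adjusted p = 0.00377). Of 18 members 0 rose and 3 fell (0 and 6 over the list alone), with SCD (−0.20) and the elongase ELOVL6 (−0.39).

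In the integrin and basement membrane list 0 of 30 members rose and 9 fell (2 and 13 over the list alone). It was shifted down (camera adjusted p = 2.7e-09), with the integrin subunit ITGA1 (−0.52) and LAMB1 (−0.32). Higher at the preset correlation only were FOXO and PI3K feedback (8 of 24 rose and 3 fell, 13 and 4 over the list alone, camera adjusted p = 0.000584, with FOXO3 at 0.47), hypoxia (3 of 24 rose and 2 fell, camera adjusted p = 0.0325, with P4HA1 at 0.43) and glycolysis (4 of 19 rose and 0 fell, 6 and 0 over the list alone, camera adjusted p = 0.044, with PGK1 at 0.29). In turn, these lists had adjusted p = 0.056, 0.41 and 0.6 with an estimated correlation. At the preset correlation only, those called lower were MAPK feedback (1 of 24 rose and 3 fell, 1 and 5 over the list alone, camera adjusted p = 0.044, with CCND1 at −0.21), mesenchymal transition (0 of 20 rose and 2 fell, camera adjusted p = 0.044, with fibronectin FN1 at −0.74), luminal differentiation (1 of 21 rose and 5 fell, 1 and 8 over the list alone, camera adjusted p = 0.000202, with CLCA2 at −1.30) and autophagy and lysosome (0 of 24 rose and 6 fell, 2 and 7 over the list alone, camera adjusted p = 0.044, with the autophagy protein WIPI1 at −0.32). As listed, they had adjusted p = 0.41, 0.41, 0.084 and 0.15 with an estimated correlation. The kidney genes LRP2 (−2.69), CUBN (−2.48), SLC22A8 (−2.20) and ANPEP (−2.15) fell, while UMOD averaged 15.5 ± 11.1 CPM in primed and treated and 8.33 ± 6.62 in treated aggregates. With only the groups compared in the fit 2050 genes passed, while 780 passed without treated replicate 1 (with 7 lists), 820 without primed and treated replicate 1 and 695 without primed and treated replicate 2. MT1G (1.81) and FN1 (−0.74) did not pass with only the compared groups fitted, LTF (−3.75) did not pass with limma voom, AKAP12 did not pass with only the compared groups fitted (−3.47) and without the MYH7 libraries (−3.46), CDKN1B (0.17) did not pass with RLE size factors, ERBB2 passed with DESeq2 and with only the compared groups fitted and VEGFA passed with only the compared groups fitted and without the MYH7 libraries.

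Primed and treated aggregates were compared with primed ones, for the response of primed aggregates to a later dose. HSPA5, an ER chaperone, averaged 910.4 ± 16.5 CPM against 1624 ± 207 (log2 −0.84, SE 0.059, edgeR adjusted p = 3.29e-12), and HSPA8, a cytosolic chaperone, 1647 ± 46.9 CPM against 1015 ± 108 (log2 0.70, SE 0.059, edgeR adjusted p = 6.56e-11). The antioxidant enzyme NQO1 averaged 369 ± 12.9 CPM against 257 ± 20.5 (log2 0.53, SE 0.052, edgeR adjusted p = 2.08e-09). ERBB2 averaged 8198 ± 310.0 CPM against 8274 ± 281 and did not pass (log2 −0.013, SE 0.053, edgeR adjusted p = 0.884). 17 of 23 NRF2 genes rose by edgeR, and 12 of 24 cholesterol synthesis genes fell. The edgeR test called 4754 genes, 2383 higher and 2371 lower. With no count in primed aggregates, UMOD was at least 306-fold higher and the complement component C7 at least 49-fold. With no count in primed and treated aggregates, POSTN was at least 471-fold lower, ISL1 at least 56.8-fold and SERPINB9 at least 49.2-fold. Of the genes followed in each comparison, EGFR (−0.34), CDKN1B (−0.30), MKI67 (−0.35) and VEGFA (−0.21) fell. ERBB3 (−0.10, adjusted p = 0.146), CCND1 (−0.004, adjusted p = 0.96) and CD274 (−0.20, adjusted p = 0.565) did not pass in edgeR.

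Of 29 lists, 9 were called by camera, 4 higher and 5 lower. In the NRF2 list 17 of 23 members rose and 1 fell. It was shifted up (camera adjusted p = 1.1e-08), with NQO1 (0.53) and transketolase TKT (0.51). Called higher with the preset correlation alone were basal and squamous (8 of 15 rose and 1 fell, 9 and 2 over the list alone, camera adjusted p = 0.000588), stem cell (6 of 18 rose and 2 fell, 8 and 2 over the list alone, camera adjusted p = 0.0238) and heat shock (5 of 16 rose and 1 fell, camera adjusted p = 0.0217). Taken one by one, adjusted p = 0.064, 0.068 and 0.48 with an estimated correlation.

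Lower at the preset correlation only were G2/M (0 of 27 rose and 15 fell, 0 and 17 over the list alone, camera adjusted p = 0.00025), hypoxia (2 of 24 rose and 13 fell, 2 and 15 over the list alone, camera adjusted p = 1.09e-06), cholesterol synthesis (2 of 24 rose and 12 fell, 2 and 15 over the list alone, camera adjusted p = 0.000191), mesenchymal transition (1 of 20 rose and 10 fell, 2 and 11 over the list alone, camera adjusted p = 0.000249) and ATF4 and unfolded protein (1 of 26 rose and 16 fell, camera adjusted p = 3.5e-09). In this order, adjusted p = 0.48, 0.06, 0.06, 0.13 and 0.13 with an estimated correlation. UMOD and RBFOX1 among the rises and POSTN, TYRP1, GPR143 and ACTA2 among the falls separate the 2 sets. The groups fell in different library sets, the treated one was 24 h older, and without primed replicate 1 14 lists were called. UMOD did not pass with only the compared groups fitted and MKI67 (−0.35) did not pass without the MYH7 libraries.

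**Figure D3:**
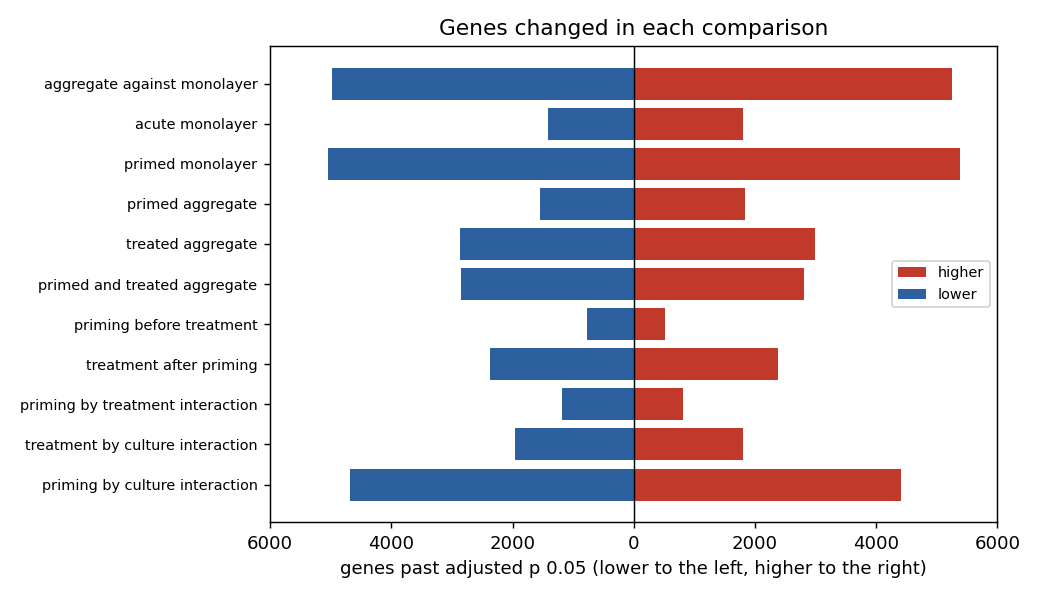
Number of genes past an edgeR adjusted p of 0.05 in each comparison, lower to the left of 0 and higher to the right. The 8 pairwise comparisons called 1274 to 10431 genes and the 3 differences between responses 1992 to 9101.

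Shared genes were counted to ask whether the same genes move in both cultures, each pair of comparisons having no library in common. The genes higher in acutely exposed monolayers and in treated aggregates shared 813 genes against 337.5 if independent (odds ratio 4.53, Fisher's exact two-sided p = 5.25e-168), and those lower 398 genes against 254.9 if independent (odds ratio 1.91, Fisher's exact two-sided p = 8.89e-23). ERBB2, ERBB3, GRB7, KRT23 and PIP were higher in both, and of 1640 genes called in both, 73.8% moved the same way. Genes higher in primed monolayers and in primed aggregates shared 565 genes against 618.8 if independent (odds ratio 0.86, Fisher's exact two-sided p = 0.00498), and those lower 304 genes against 487.9 if independent (odds ratio 0.501, Fisher's exact two-sided p = 4.59e-28). Of 2638 called in both, 1769 moved in opposite directions (MCM3 1.67 and −0.40). In both pairs 1 comparison crosses the sets, so set and exposure cannot be told apart. Acutely exposed monolayers and primed aggregates, a pair added after the data were seen and within 1 library set, shared 612 genes against 206.8 if independent (odds ratio 5.45, Fisher's exact two-sided p = 5.65e-166) higher and 315 genes against 137.5 if independent (odds ratio 3.08, Fisher's exact two-sided p = 2.2e-49) lower. Here 78% of 1189 genes moved the same way, ERBB2, ERBB3, GRB7 and ITGB5 higher in both. Across all tested genes Pearson's r of the fold changes was 0.12 in the first pair, −0.13 in the second and 0.070 in the third. Genes are not independent of one another, so these p values overstate the evidence.

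The change with treatment in primed aggregates was set against that in unprimed ones, a difference in which only a constant log2 shift between the library sets cancels. MKI67 averaged 32.4 ± 3.26, 39.2 ± 6.69, 54.2 ± 6.67 and 30.9 ± 1.71 CPM in untreated, primed, treated, and primed and treated aggregates, a log2 difference of −1.09, SE 0.15, edgeR adjusted p = 4.26e-05. ERBB2 averaged 6189 ± 426, 8274 ± 281, 8992 ± 140.0 and 8198 ± 310.0 CPM in the same order, a difference of −0.55, SE 0.075, edgeR adjusted p = 2.7e-06. The difference was positive in 16 of 24 hypoxia genes and negative in 25 of 27 G2/M genes by edgeR. The edgeR test of the difference called 1992 genes, 807 positive and 1185 negative. The most positive fitted differences were in STAC2, IL20, PLA2G4D and UPB1 and the most negative in CRTAC1, PROS1, AKAP12 and ISM1. Among the genes followed throughout, the difference was positive for VEGFA (0.46) and negative for ERBB2 (−0.55), ERBB3 (−0.62), CCND1 (−0.23) and MKI67 (−1.09), while EGFR (0.082, adjusted p = 0.601), CDKN1B (−0.045, adjusted p = 0.792) and CD274 (0.38, adjusted p = 0.539) did not pass in edgeR.

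Camera called 19 lists on this difference. The HER family list differed downward (camera adjusted p = 0.000556), positive in 0 of 16 members and negative in 4 (0 and 6 over the list alone). The G2/M list differed downward (camera adjusted p = 1.43e-35), positive in 0 of 27 members and negative in 25 (0 and 26 over the list alone). The hypoxia list differed upward (camera adjusted p = 3.89e-19), positive in 16 of 24 members and negative in 1 (19 and 2 over the list alone). The glycolysis list differed upward (camera adjusted p = 5.46e-15), positive in 11 of 19 members and negative in 0 (14 and 2 over the list alone). The fatty acid synthesis list differed downward (camera adjusted p = 0.00541), positive in 0 of 18 members and negative in 4 (1 and 5 over the list alone). The integrin and basement membrane list differed downward (camera adjusted p = 9.75e-14), positive in 1 of 30 members and negative in 15 (1 and 19 over the list alone). The NRF2 list differed upward (camera adjusted p = 0.000817), positive in 7 of 23 members and negative in 2 (10 and 2 over the list alone). The MYC and ribosome biogenesis list differed upward (camera adjusted p = 0.000235), positive in 5 of 26 members and negative in 0 (10 and 0 over the list alone). The autophagy and lysosome list differed downward (camera adjusted p = 0.00541), positive in 1 of 24 members and negative in 8 (2 and 8 over the list alone). Higher with the preset correlation alone were oxidative phosphorylation (camera adjusted p = 0.00541), basal and squamous (camera adjusted p = 0.0187) and heat shock (camera adjusted p = 0.00955). In turn, these lists had adjusted p = 0.43, 0.15 and 0.27 with an estimated correlation. Lower with the preset correlation alone were MAPK feedback (camera adjusted p = 0.012), cholesterol synthesis (camera adjusted p = 0.00597), type I interferon (camera adjusted p = 0.0105), epithelial junction (camera adjusted p = 0.00955), mesenchymal transition (camera adjusted p = 0.0155), YAP/TAZ and actin (camera adjusted p = 0.00955) and luminal differentiation (camera adjusted p = 0.00825). As listed, they had adjusted p = 0.22, 0.096, 0.22, 0.15, 0.26, 0.35 and 0.19 with an estimated correlation. CRTAC1, PROS1 and ISM1 were, of these 4 groups, highest in primed aggregates, as was the melanocyte gene TYRP1 (6.63 ± 1.37, 23.9 ± 7.21, 0.13 ± 0.112 and 0.108 ± 0.0575 CPM, ordered as MKI67 above). PLA2G4D, AKAP12, CCND1 (−0.16) and VEGFA (0.22) did not pass without the MYH7 libraries.

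The response of aggregates to a later dose was set against that of monolayers to the acute exposure, though dose, age and library set differ too. VEGFA averaged 169 ± 7.44, 241 ± 17.9, 369 ± 49.6 and 231 ± 0.876 CPM in untreated and acutely exposed monolayers and untreated and treated aggregates, a log2 difference of −1.19, SE 0.093, edgeR adjusted p = 7.39e-11. MKI67 averaged 193 ± 5.28, 165 ± 3.87, 32.4 ± 3.26 and 54.2 ± 6.67 CPM in that order, a difference of 0.97, SE 0.14, edgeR adjusted p = 3.03e-05. It was negative in 17 of 24 hypoxia genes and positive in 26 of 27 G2/M genes by edgeR. The edgeR test of the difference called 3757 genes, 1804 positive and 1953 negative. The most positive fitted differences were in AQP2, MYT1L, SLC22A8 and UGT1A9 and the most negative in ISL1, LRRN4CL, POSTN and TYR. Among the genes followed throughout, the difference was positive for MKI67 (0.97) and negative for EGFR (−0.65), CCND1 (−0.21), CDKN1B (−0.47) and VEGFA (−1.19), while ERBB2 (0.18, adjusted p = 0.0843), ERBB3 (0.017, adjusted p = 0.901) and CD274 (−0.26, adjusted p = 0.652) did not pass in edgeR.

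Camera called 10 lists on this difference. The MAPK feedback list differed downward (camera adjusted p = 1.95e-13), positive in 1 of 24 members and negative in 15. The G2/M list differed upward (camera adjusted p = 1.2e-30), positive in 26 of 27 members and negative in 0. The hypoxia list differed downward (camera adjusted p = 4.03e-34), positive in 0 of 24 members and negative in 17. Higher with the preset correlation alone were cholesterol synthesis (camera adjusted p = 0.00437), NRF2 (camera adjusted p = 0.00244) and autophagy and lysosome (camera adjusted p = 0.0338). Taken one by one, adjusted p = 0.087, 0.077 and 0.087 with an estimated correlation. Lower with the preset correlation alone were FOXO and PI3K feedback (camera adjusted p = 0.000382, median 0.014 and mean −0.25), glycolysis (camera adjusted p = 6.43e-12), ATF4 and unfolded protein (camera adjusted p = 3.99e-05) and MYC and ribosome biogenesis (camera adjusted p = 0.00216). In this order, adjusted p = 0.066, 0.066, 0.29 and 0.087 with an estimated correlation. AQP2, SLC22A8 and UGT1A9 are kidney genes and MYT1L a neuronal one, and POSTN and TYR are of the other set. Without the 6 libraries with MYH7, 1178 genes passed, 530 positive and 648 negative. AQP2 did not pass with the replicate number as a block and without the MYH7 libraries, MYT1L, SLC22A8, UGT1A9, LRRN4CL, TYR and CCND1 (−0.22) did not pass without the MYH7 libraries and ERBB2 passed with limma voom, with DESeq2, without the MYH7 libraries and among genes averaging 10 CPM or more.

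The change after priming in aggregates was set against that in monolayers, of which the primed monolayers alone are of the other library set. EGFR averaged 86.4 ± 2.37, 219 ± 16.6, 314 ± 7.88 and 322 ± 36.5 CPM in untreated and primed monolayers and untreated and primed aggregates, a log2 difference of −1.30, SE 0.087, edgeR adjusted p = 1.4e-14. CCND1 averaged 273 ± 4.42, 490.3 ± 8.92, 286 ± 11.8 and 289 ± 9.87 CPM in that order, a difference of −0.83, SE 0.065, edgeR adjusted p = 5.6e-13. It was negative in 26 of 27 G1/S genes by edgeR. The edgeR test of the difference called 9101 genes, 4412 positive and 4689 negative. The most positive fitted differences were in ADAM23, GPR143, TRIM63 and TYRP1 and the most negative in GP2, NEURL3, IVL and IL36RN. Among the genes followed throughout, the difference was positive for ERBB2 (0.31), CDKN1B (0.37) and VEGFA (0.28) and negative for EGFR (−1.30), CCND1 (−0.83) and MKI67 (−0.37), while ERBB3 (0.011, adjusted p = 0.913) and CD274 (0.003, adjusted p = 0.996) did not pass in edgeR.

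Camera called 12 lists on this difference. The G1/S list differed downward (camera adjusted p = 2.4e-16), positive in 0 of 27 members and negative in 26. The basal and squamous list differed downward (camera adjusted p = 1.55e-05), positive in 0 of 15 members and negative in 12. The MYC and ribosome biogenesis list differed downward (camera adjusted p = 3.15e-06), positive in 2 of 26 members and negative in 20. Higher with the preset correlation alone were type I interferon (camera adjusted p = 0.00731), ATF4 and unfolded protein (camera adjusted p = 0.00954) and autophagy and lysosome (camera adjusted p = 0.0217). In turn, these lists had adjusted p = 0.26, 0.57 and 0.11 with an estimated correlation. Lower with the preset correlation alone were MAPK feedback (camera adjusted p = 0.0273), glycolysis (camera adjusted p = 0.00243), NF-kB target (camera adjusted p = 0.000378), epithelial junction (camera adjusted p = 0.0386), YAP/TAZ and actin (camera adjusted p = 3.1e-05) and stem cell (camera adjusted p = 0.0273). As listed, they had adjusted p = 0.32, 0.4, 0.11, 0.27, 0.21 and 0.1 with an estimated correlation. The melanocyte genes GPR143 and TYRP1 separate the sets. GP2, NEURL3, IL36RN and MKI67 (−0.35) did not pass without the MYH7 libraries.

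**Figure D4:**
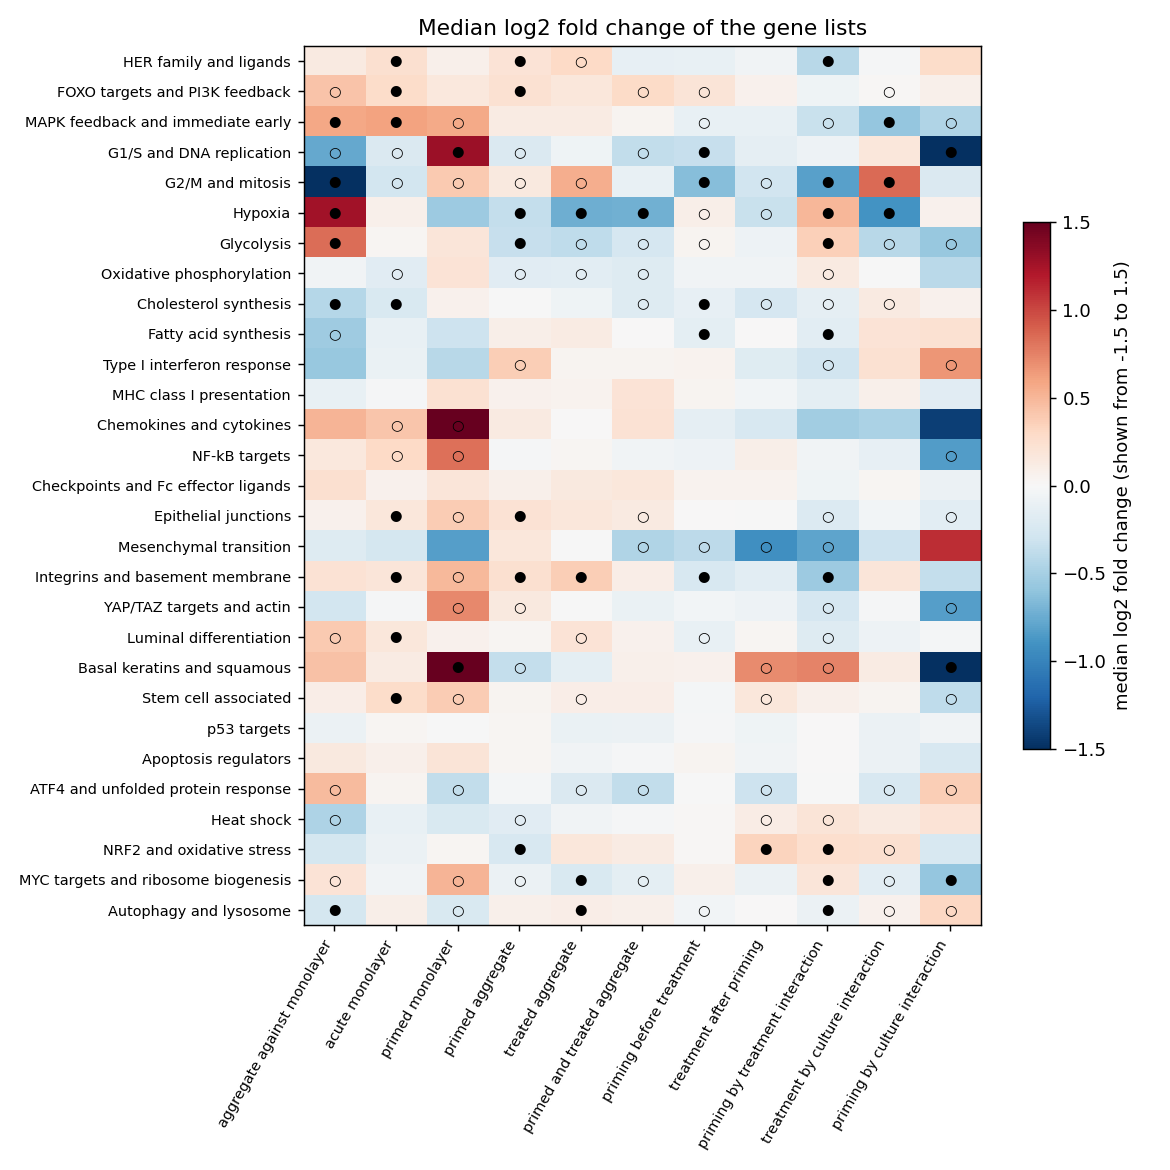
Median log2 fold change of each of the 29 pathway lists in each comparison, with filled points for lists called by camera with both the preset and an estimated correlation and open points for those called with the preset one only. The hypoxia list is higher in untreated aggregates than in monolayers and lower in primed and in treated aggregates than in untreated ones.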

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

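The tests of other splits of the libraries, of tissue transcripts, of the library set, of cycling before treatment and without the libraries with muscle transcripts were chosen only after the result was seen.

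The response to treatment differed with priming by a test of the difference itself, in 1992 genes. Fitted log2 differences were STAC2 (2.64), IL20 (2.42), PLA2G4D (2.30), UPB1 (2.28), CRTAC1 (−6.62), PROS1 (−4.64), AKAP12 (−4.60), ISM1 (−4.55), ERBB2 (−0.55), ERBB3 (−0.62), CCND1 (−0.23), MKI67 (−1.09) and VEGFA (0.46). Medians of the called lists were HER family (−0.41), MAPK feedback (−0.33), G2/M (−0.82), hypoxia (0.49), glycolysis (0.36), oxidative phosphorylation (0.14), cholesterol synthesis (−0.13), fatty acid synthesis (−0.16), type I interferon (−0.29), epithelial junction (−0.21), mesenchymal transition (−0.79), integrin and basement membrane (−0.54), YAP/TAZ and actin (−0.25), luminal differentiation (−0.19), basal and squamous (0.74), heat shock (0.19), NRF2 (0.25), MYC and ribosome biogenesis (0.18) and autophagy and lysosome (−0.084). Of these 19 lists 9 kept their call with an estimated correlation. Of 33 splits of these libraries, 1 gave as many genes and 1 as many lists, the real one included (1992 genes against at most 1345 in the others, 19 lists against 15), so a random split is excluded for both.

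The response to treatment also differed between cultures by the same kind of test, in 3757 genes, with AQP2 (12.75), MYT1L (10.03), SLC22A8 (9.89), UGT1A9 (8.96), ISL1 (−7.94), LRRN4CL (−6.95), POSTN (−6.90), TYR (−6.77), EGFR (−0.65), CCND1 (−0.21), CDKN1B (−0.47), MKI67 (0.97) and VEGFA (−1.19). List medians were FOXO and PI3K feedback (0.014), MAPK feedback (−0.58), G2/M (0.85), hypoxia (−0.90), glycolysis (−0.42), cholesterol synthesis (0.13), ATF4 and unfolded protein (−0.24), NRF2 (0.24), MYC and ribosome biogenesis (−0.16) and autophagy and lysosome (0.065). Of 33 splits 5 gave as many genes (at most 6984 against 3757) and 11 as many lists (at most 16 against 10). They mix monolayers and aggregates and cannot decide whether this difference arose at random.

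The change after priming differed between cultures in 9101 genes, tested likewise, with ADAM23 (11.50), GPR143 (10.84), TRIM63 (10.81), TYRP1 (10.28), GP2 (−8.51), NEURL3 (−7.10), IVL (−6.96), IL36RN (−6.57), ERBB2 (0.31), EGFR (−1.30), CCND1 (−0.83), CDKN1B (0.37), MKI67 (−0.37) and VEGFA (0.28). List medians were MAPK feedback (−0.45), G1/S (−1.63), glycolysis (−0.56), type I interferon (0.66), NF-kB target (−0.83), epithelial junction (−0.16), YAP/TAZ and actin (−0.83), basal and squamous (−2.27), stem cell (−0.38), ATF4 and unfolded protein (0.37), MYC and ribosome biogenesis (−0.58) and autophagy and lysosome (0.31). Of 33 splits, the real one included, 1 gave as many genes (9101 against at most 7096) and 8 as many lists (12 against at most 14). They too mix both cultures and cannot decide whether this is random. Fitted differences of genes near 0 counts in a group, among them AQP2, UGT1A9, ISL1, POSTN, GPR143 and IL36RN, depend on the prior count and are no bounds.

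The first pattern is that UMOD and SNAP25 (kidney, brain) marked 9 libraries and TYRP1 and POSTN (melanocyte, mesenchymal) the other 12. MYH7 marked 6 of these. Against exposure alone as the cause, 6 kidney genes near 0 in the untreated groups stood in acutely exposed monolayers and primed aggregates at 0.37% of their level in the 3 other exposed groups, and against longer culture alone, in primed aggregates at 0.61% of that in primed monolayers. They varied between replicates a median of 2.93 times as much as their 100 nearest genes in level, so RNA or reads of other tissues is a candidate source. AU565 libraries of both sets had 3 of 16 kidney, 2 of 12 muscle, 2 of 9 melanocyte, 2 of 12 brain and 4 of 14 mesenchymal panel genes over 1 CPM. The set and priming cannot be told apart as the cause of the primed monolayer changes (r = 0.34 across 9520 genes, which are not independent, with the changes of treatment after priming), because each of these comparisons crosses the sets.

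The second pattern is the lower hypoxia list in exposed aggregates. For primed aggregates (median −0.35) the design argues against the library set, since both groups belong to 1 set. Neither 1 library (highest median −0.335 over 6 fits) nor the muscle libraries (median −0.423 without them) accounts for it. For treated aggregates (median −0.727) set, age and treatment cannot be told apart. A change of oxygen supply in smaller or looser aggregates, or lower HIF signalling after trastuzumab, may underlie it and was not tested.

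The third pattern is the lower G2/M list in primed and treated than in treated aggregates. Both groups belong to 1 set and 1 age, so the design argues against either as its source. The median of −0.64 stayed at −0.608 or lower without any 1 library and was −0.648 with RLE size factors. Fewer cycling cells before treatment stay possible. In primed against untreated aggregates the list was not lower (lowest median 0.082 over 6 fits without 1 library, 0 of 27 genes fell). G1/S was lower (median −0.22, 10 of 27 fell). The G2/M response to a later dose may differ with priming (median difference −0.82 above), and how priming would act was not tested.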

How the results depend on the processing

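The fits without the libraries with muscle transcripts and among genes averaging 10 CPM or more were chosen only after the result was seen. No alternative turned the direction of a named gene. With an estimated correlation the lists called were 6 for aggregate against monolayer, 8 for acute monolayer, 2 for primed monolayer, 7 for primed aggregate, 4 for treated aggregate, 1 for primed and treated aggregate, 5 for priming before treatment, 1 for treatment after priming, 9 for priming by treatment, 3 for treatment by culture and 3 for priming by culture, an estimate from few residual degrees of freedom. With only the groups compared, 2177 genes were called for primed aggregate and 2050 for priming before treatment. Without the 6 libraries with muscle transcripts, 727 were called for acute monolayer, 2176 for primed aggregate and 1178 for treatment by culture, with fewer libraries in each. The cause was not tested. Leaving out 1 replicate gave 695 to 1138 genes and 7 to 11 lists for priming before treatment and 8 to 14 lists for treatment after priming. For priming before treatment 780 genes were called without treated replicate 1, 820 without primed and treated replicate 1 and 695 without primed and treated replicate 2, and the 14 lists for treatment after priming came without primed replicate 1. All other gene and list counts stayed within 1.5 times under the alternatives run.

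With the replicate number as a block, 10166, 3157, 10374, 3288, 5783, 5617, 1228, 4708, 1909, 3685 and 9042 genes were called, in the order of the list counts above. The labels do not say that equal numbers were paired, and the mean correlation of their deviations was −0.004 over 63 pairs.

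Of the values of genes named by the rule, limma voom ended 7 calls and made 3, of 521. DESeq2 ended 1 and made 4 of 506, with 15 given no adjusted p. A fit of only the groups compared ended 10 and made 3, the block ended 3, RLE size factors 1 and no count filter 0. Without the muscle libraries 57 ended and 2 were made, and among genes averaging 10 CPM or more 2 were made. Leaving out 1 replicate ended 124 and made 8, over 3432 values. With the number of such fits and the highest edgeR adjusted p in brackets, these ended for CDKN1B (3, 0.075) and EGFR (1, 0.052) in acute monolayer, for CLEC3B (4, 0.184), DES (5, 0.103), DNAJA1 (1, 0.0527), HSP90AA1 (2, 0.0542) and IFI27 (5, 0.0662) in primed aggregate, for NAT8 (2, 0.0577), TNNI3 (5, 0.152) and UMOD (1, 0.0588) in primed and treated aggregate, for CDKN1B (4, 0.228) in primed monolayer, for AKAP12 (4, 0.12), ALDOC (4, 0.0934), BHLHE41 (6, 0.205), CDKN1B (5, 0.268), ELOVL6 (2, 0.166), EPHA2 (2, 0.0768), FASN (4, 0.0981), GABRR2 (2, 0.0733), ITGA5 (4, 0.252), MT1G (1, 0.0886), NR2F2-AS1 (5, 0.148), SCD (3, 0.0949) and UPB1 (1, 0.0688) in priming before treatment, for MKI67 (6, 0.0921) and VEGFA (1, 0.0503) in priming by culture, for AKAP12 (6, 0.0865), CCND1 (4, 0.0651), IL20 (2, 0.0647), ISM1 (1, 0.0783) and PROS1 (2, 0.097) in priming by treatment, for UMOD (5, 0.101) in treated aggregate, for MKI67 (3, 0.112) and VEGFA (2, 0.0616) in treatment after priming, for AQP2 (4, 0.147), MYT1L (1, 1), SLC22A8 (1, 1) and UGT1A9 (1, 1) in treatment by culture. At this depth 3 counts are worth 0.111 to 0.2 CPM, so differences between genes below that are not detectable.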

Other observations

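The tests of other splits of the libraries were chosen only after the result was seen. Of 38 cytosolic ribosomal protein genes, 38 rose in untreated aggregates against monolayers (edgeR, median log2 0.52), 36 fell in treated aggregates (median −0.42) and 25 in primed and treated ones (median −0.25). In primed and treated against treated aggregates 8 rose (23 adjusted over the list alone) and after treatment of primed aggregates 19 fell, while 1 rose and 1 fell in acutely exposed monolayers, 18 and 5 in primed monolayers and 0 and 3 in primed aggregates. Of 13 genes encoded in the mitochondrial genome, 9 rose in treated aggregates and 4 fell in primed and treated against treated ones. Of 13 replication-dependent histone genes, 10 fell in primed monolayers (median −1.13), where 26 of 27 G1/S genes rose. Lists of p53 targets, apoptosis regulators and checkpoint ligands were not called in any of the 11 comparisons. Of 10 fibroblast markers, in the order of the pairwise comparisons, 0 and 3, 1 and 1, 2 and 5, 1 and 0, 2 and 4, 2 and 3, 1 and 0 and 1 and 3 rose and fell, and of 7 endothelial markers 3 and 3, 2 and 1, 4 and 2, 0 and 2, 1 and 2, 2 and 1, 1 and 1 and 2 and 1.

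ERBB2 and GRB7, neighbours in the amplified region of chromosome 17, rose in acutely exposed monolayers (log2 0.36 and 0.89). The other 12 tested genes within 200 kb had a median of 0.075, and 1 of them rose by edgeR (ORMDL3, 0.19), which argues against a rise of the whole neighbourhood. In treated aggregates ERBB2 (0.54) and GRB7 (0.73) rose while MIEN1 between them fell (−0.36).

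The 6 libraries of a pairwise comparison make 10 splits of 3 against 3, too few for a share under 0.05. The real split against the highest of the others gave 10229 against 0 genes and 13 against 12 lists for aggregate against monolayer, 3222 against 17 genes and 13 against 11 lists for acute monolayer, 10431 against 0 genes and 13 against 13 lists for primed monolayer, 3379 against 21 genes and 15 against 17 lists for primed aggregate, 5856 against 0 genes and 11 against 10 lists for treated aggregate, 5671 against 0 genes and 10 against 12 lists for primed and treated aggregate, 1274 against 0 genes and 12 against 11 lists for priming before treatment and 4754 against 1 genes and 9 against 14 lists for treatment after priming. The number of splits with as many genes was 1 in each, and with as many lists 1, 1, 2, 2, 1, 2, 1 and 4 in that order.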
